A study of Caenorhabditis elegans with 2 samples.

How the data were processed

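ChIP-seq peak lists of GFP-tagged REPO-1 from 2 biological replicates of whole young adult worms were analysed. Chromatin was fragmented by sonication, per the labels. The deposited files were a region list for each replicate, a region list called on both replicates together, and a list of replicated regions derived from these by IDR, each on ce11 and on ce10. The replicate lists and the pooled list, meant as input for IDR, had no significance threshold and held exactly 30000 summits each, at slightly fewer distinct regions. The derivation and assemblies are per the file headers and the text files deposited with each sample. Per the same text files, the region lists derive from the replicates' alignments and a further alignment that also enters tracks named as normalized to a control. These tracks were not used here. The aligner, the peak caller, their versions, the IDR threshold and the sequencing depth are not given in the sources used here.

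Each list has 1 row per summit with its region, a signal value deposited by the authors, whose scale is not stated, and the −log10 of a q-value deposited by the authors, which was tied at its maximum for 1354 of the 1789 replicated peaks. The signal was therefore used for ranking, with the q-value as an alternative. The replicated list consisted of the 1789 strongest peaks of the pooled list, so its ranks are those of the pooled replicates. Replicated here names membership of this list, and not every peak in it was found in both replicates. Of the 1789, 1781 overlapped a region of replicate 2's full list, and 67 overlapped none of the 1789 strongest of either replicate. Signal values depend on the depth and normalisation of each list and were not compared between lists. A region listed with several summits was kept as several peaks. Coordinates are 1-based on ce11, which is the same assembly as WBcel235. Gene models came from Ensembl release 115 on WBcel235 and sequence from the RefSeq copy of that assembly, with all regions lying within its chromosome lengths. The mitochondrial genome was left out. No coordinates were converted between builds, and the ce10 lists were used only for counts and overlaps within ce10.

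A protein-coding or non-coding gene was called occupied when a summit of the replicated list lay from 500 bp upstream to 200 bp downstream of the 5′ end of any of its transcripts. Of 19973 protein-coding genes, 697 were occupied. Gene lists were compared with all other protein-coding genes, and non-coding classes with protein-coding genes, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 19 lists or 9 classes. Of the symbols in the lists, 2 in the splicing list and 1 in the RNA polymerase II list matched no gene. Occupied neighbours can share 1 peak between divergent genes, so rotation of the calls along the gene order (10000 rotations) was an alternative for protein-coding genes. Position classes and positions along genes were tested against 1000 circular shifts of all summits within each chromosome, by at least 20000 bp, with adjustment over the classes or parts. Classes were assigned in the order promoter, within 200 bp of a non-coding gene, coding exon, UTR, intron, within 500 bp downstream of a 3′ end, and other. Replicate overlap used the 1789 strongest peaks of each replicate and a minimum overlap of 1 bp. Base composition was compared by a permutation test with 100000 resamples. Shares have Wilson 95% intervals, and a count of 0 is given the limit that 3 counts would set.

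Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took repo-1, the protein-coding gene with the nearest 5′ end within 1000 bp of each of the 25 strongest peaks (otherwise the position and any non-coding gene within 200 bp), up to 4 occupied members with the strongest peaks of each list, and up to 2 of each non-coding class. Alternatives were promoter windows of 1000 and 200 bp upstream or 200 and 100 bp downstream, assignment to the nearest 5′ end, peaks at or above the median signal, a stricter overlap, lists from a single replicate, genes without a same-strand gene ending within 500 bp upstream, and a background of genes with a region of the pooled list. A window around 3′ ends, from 200 bp upstream to 500 bp downstream, and counting a region with several summits once were added after the data were seen. With 1 group there is no test across samples, and the p-values measure departures over peaks or genes within this peak list. No paired analysis applied.

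The computations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. They were tested on simulated data. In 1 simulated set of 1800 peaks over 19973 genes, 3 lists given extra peaks were all recovered and 0 others were called, and in 50 sets of random peaks 1 of 950 list tests was called. The 3 lists were given peaks far more often than other genes, so their recovery does not cover weaker differences. Random peaks fell uniformly along the chromosomes, so those sets do not give the rate of false calls for peaks that gather at promoters. Of 500 random sequences, all 50 with a planted motif were found, as were 8 of the 450 others.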

Results

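Chromatin association of REPO-1 was measured by ChIP-seq in whole young adult Caenorhabditis elegans. REPO-1 is the worm ortholog of SF3A2, a subunit of the SF3a complex that acts in the U2 snRNP during pre-mRNA splicing. The worms carried an integrated transgene encoding REPO-1 with a C-terminal GFP-FLAG tag, and the tagged protein was pulled down with an antibody against GFP. There was 1 group with 2 biological replicates, each from mixed-sex worms collected 53 hours after synchronisation by starvation at the L1 larval stage. No untagged strain, input library or other genotype formed a comparison group, so peaks were compared with shifted positions, with annotated classes and between replicates. The deposited lists held positions and peak values but no read counts, so sequencing depth is unknown, and the Wilson intervals below cover counting error over peaks or genes only. Signal values are the authors' own values for each peak and were used only to rank or describe peaks within a list.

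The strongest replicated REPO-1 peaks lay at ribosomal protein genes, at spliced leader RNA and snoRNA genes, and at positions on the X chromosome away from protein-coding 5′ ends. The highest signal in the list, 1217.6, was 304 bp upstream of rpl-3, the gene of ribosomal protein L3, at chromosome III position 3867550 (ce11, peak 3867265 to 3867743), and this peak ranked 1 in the replicated list and in each replicate's own list. The peak of rank 2 (I: 4171991 to 4172718, signal 997.0) overlapped sls-2.4, a gene of the SL2 spliced leader RNA that is trans-spliced onto downstream genes of operons, and its nearest protein-coding 5′ end was that of egg-5, 754 bp away. The peak of rank 4 (II: 5844645 to 5845021, signal 915.9) covered another SL2 RNA gene, sls-2.1, with the nearest protein-coding 5′ end at ZK1248.17. The peaks of rank 6 and 12 lay on chromosome V at the snoRNA genes ZK994.7 and C51F7.4. Of the 25 strongest peaks, 9 were on X, and 8 of those had no protein-coding 5′ end within 1000 bp. They included a peak inside mom-1 (rank 3, summit X: 6296572, intronic), whose product is related to the Wnt acyltransferase Porcupine, and intergenic peaks with summits at X: 13700860 (rank 5) and X: 11094194 (rank 8). On autosomes, the peaks of rank 11 to 24 that had a protein-coding 5′ end within 1000 bp lay upstream of Y17G9B.5, tasp-1, Y55F3AR.2, Y22D7AL.10, drr-2, rpl-15, rpl-35 and the cytochrome c oxidase subunit gene cox-5A. Besides the peak at C51F7.4, those without one were inside ppfr-1 at the non-coding gene anr-20 (rank 16), in a coding exon of dos-3 (rank 20) and at linc-128 (rank 22). All 25 peaks were within the top 41 of replicate 1 and the top 40 of replicate 2.

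In all, the replicated list (thresholded by the irreproducible discovery rate, IDR) held 1789 peaks at 1759 distinct regions, with a median width of 436 bp, and covered 0.719% of the nuclear genome. Signal ran from 131.5 to 1217.6 with a median of 173.3. Chromosome III had the highest density, 23.7 peaks per Mb, and chromosome V the lowest, 13.7 per Mb. The counts were 274 on I, 280 on II, 327 on III, 321 on IV, 287 on V and 300 on X. The list made on the older build ce10 held 1831 peaks, with 331 on III and 306 on X.

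The replicates placed their strongest peaks at largely shared positions. Of the 1789 replicated peaks, 1488 (83.2%, Wilson 95% interval 81.4 to 84.8) overlapped one of the 1789 strongest peaks of replicate 1 by at least 1 bp, and 1385 (77.4%, interval 75.4 to 79.3) did so for replicate 2. For 1151 peaks (64.3%, interval 62.1 to 66.5) the overlap held in both replicates, against a mean of 0.0238% after circular shifts (permutation p = 0.002, two-sided, the smallest that 1000 shifts can give). The replicated list holds the strongest peaks called on both replicates together, so it is not independent of either replicate. The replicates' own lists were therefore also set against each other: 1169 of the 1789 strongest peaks of replicate 1 (65.3%) overlapped one of the 1789 strongest of replicate 2, against 1.48% after shifting (p = 0.002, same permutation test). Across 1781 replicated peaks found in both full lists, the replicates' signal values had a Spearman rho of 0.624, and across 2213 regions strong in either replicate the rho was 0.466. These are correlations across peaks, which are not independent replicates.

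Promoters, non-coding genes and the sequence just downstream of genes held more REPO-1 summits than shifted positions did, and introns and intergenic sequence held fewer. Summits from 500 bp upstream to 200 bp downstream of a protein-coding 5′ end made up 34.2% of the list (611 peaks, interval 32.0 to 36.4), against 16.3% of shifted summits. Summits within 200 bp of a non-coding gene made up 19.3% (345 peaks) against 6.46%. A further 11.0% (196 peaks) lay within 500 bp downstream of a protein-coding 3′ end, 2.80 times the shifted share of 3.91%. UTRs held 4.42% against 3.10%. Coding exons held 14.1% against 20.2%, introns 9.28% against 28.0%, and the remaining sequence 7.77% against 22.04%. Each of the 7 classes differed from the shifts (permutation test, two-sided, adjusted p = 0.002, the smallest that 1000 shifts can give). The UTR difference was not past the threshold among peaks at or above the median signal (3.13%, permutation adjusted p = 1), nor the coding exon difference without replicate 2 (18.2%, adjusted p = 0.0699). On X, 56 of 300 summits were in promoter windows and 100 at non-coding genes, while on III these counts were 121 and 56 of 327. Counts by chromosome were not set against shifts. X holds 276 of the 612 tRNA genes, so the counts also depend on where genes of each class lie.

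**Figure D1:**
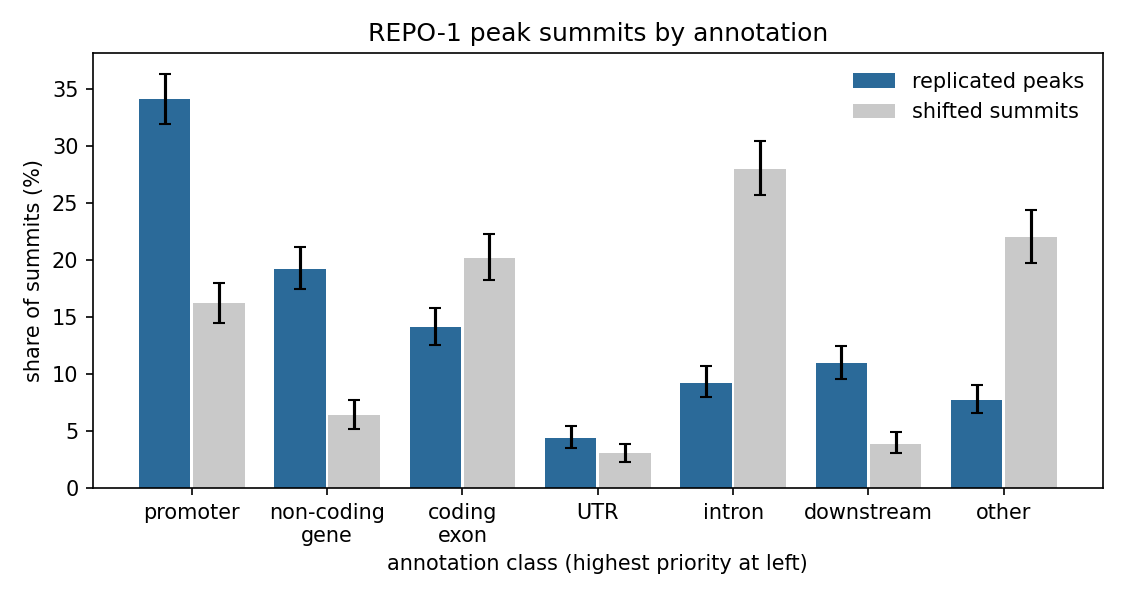
Share of replicated REPO-1 summits (blue, in percent of 1789) and of circularly shifted summits (grey) in each annotation class; blue error bars are Wilson 95% intervals and grey error bars span the central 95% of 1000 shifts. Promoter windows hold 34.2% of summits against 16.3% of shifted summits, and introns 9.28% against 28.0%.

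Within the bodies of long protein-coding genes, REPO-1 summits gathered at the ends, and most of all at the 3′ end. Summits upstream of the 5′ end or beyond the 3′ end lie outside the gene body and were not counted. Those inside it were counted even when in the promoter window of another gene. The shares therefore do not rank whole 5′ against whole 3′ regions. Genes of 2000 bp or longer contained 690 summits, and 33.5% of these (231, interval 30.1 to 37.1) were in the last of 5 equal parts of the gene body, against 20.2% of shifted summits (permutation test, adjusted p = 0.0025). The part nearest the 5′ end held 23.8% (164 summits) against 20.1% (permutation adjusted p = 0.012), and the middle part held 11.9% (82 summits) against 19.9% (adjusted p = 0.0025). The chaperone gene hsp-1, chosen for display after its values were seen (IV: 17278959 to 17281330, plus strand), encoding an Hsc70 protein, carried peaks at both ends: a summit 347 bp upstream of its 5′ end with a signal of 517.9 (rank 55) and a summit 48 bp beyond its 3′ end with a signal of 524.1 (rank 53). Both summits lay just outside its gene body. The upstream peak also overlapped another annotated gene, F26D10.23, and its summit lay nearer to that gene than to hsp-1. A weaker peak (rank 1637) lay inside hsp-1, and the region at the 3′ end also overlapped the 3′ end of nra-1, on the minus strand. In genes of 4000 bp or longer the last part still held more than shifted summits, 29.3%, but the 5′ part (23.04%) no longer passed the test, with a permutation adjusted p of 0.102.

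**Figure D2:**
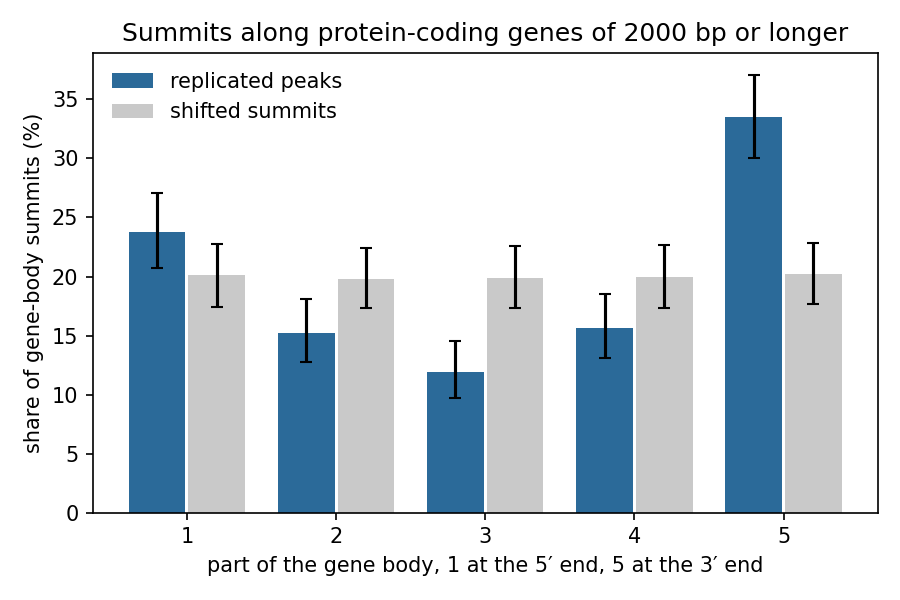
Share of gene-body summits (percent of 690) in 5 equal parts of protein-coding genes of 2000 bp or longer, for replicated REPO-1 peaks (blue, Wilson 95% intervals) and shifted summits (grey, central 95% of 1000 shifts). The part at the 3′ end holds 33.5% and the middle part 11.9%.

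**Figure D3:**
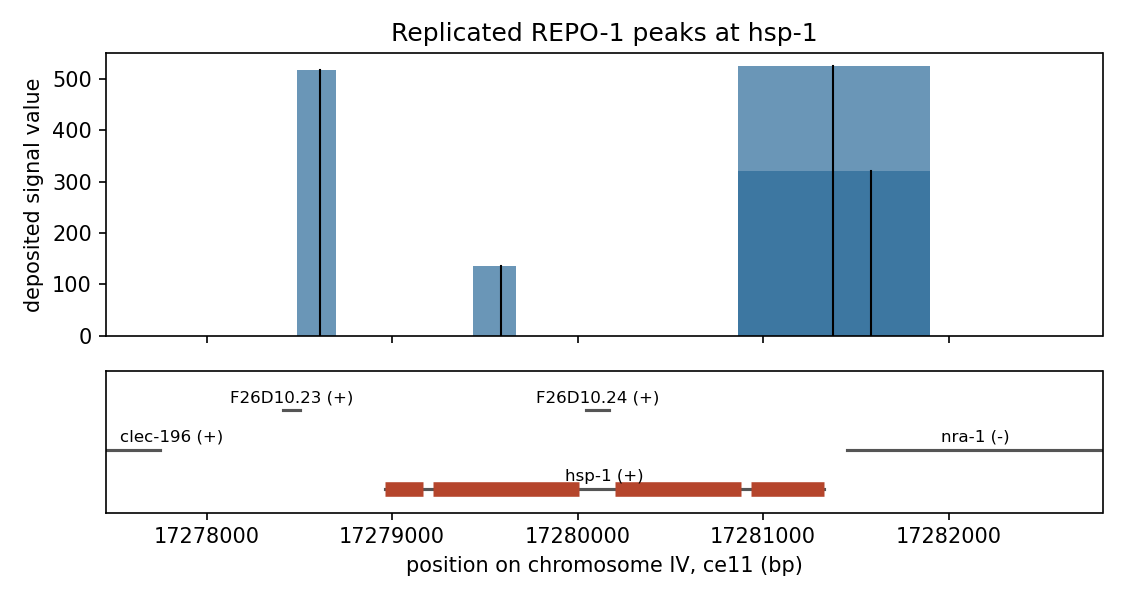
Replicated REPO-1 peaks around hsp-1 on chromosome IV (ce11): the upper panel gives each peak's deposited signal value over its width, with black lines at summits, and the lower panel shows exons of hsp-1 (red) and other annotated genes (lines, strand in brackets). Signals of 517.9 and 524.1 stand upstream and at the 3′ end of the gene, and the wide region at the 3′ end has another summit with a signal of 319.8.

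Genes for protein synthesis, protein folding, respiration and splicing carried REPO-1 peaks at their 5′ ends more often than other protein-coding genes. The ribosomal protein, respiratory chain and splicing calls ended under some other settings, given in the next paragraph. Peaks that also lay near a non-coding gene were not set apart. Of 79 ribosomal protein genes, 21 were occupied (26.6%, interval 18.1 to 37.2), against 3.40% of all others (odds ratio 10.3, Fisher's exact test, adjusted p = 3.93e-12). Besides rpl-3, the strongest were rpl-20 (300 bp upstream, rank 11, a peak nearer to Y17G9B.5, at 162 bp), rpl-15 (349 bp, rank 18) and rpl-35 (439 bp, rank 23). Of 59 heat shock and chaperone genes, 14 were occupied (odds ratio 8.76, exact adjusted p = 6.86e-08), led by the chaperonin subunit gene cct-8 (rank 14, a peak 438 bp upstream that lay nearer to Y55F3AR.2, at 183 bp), hsp-1 (rank 55) and the DnaJ-type co-chaperone genes dnj-9 (rank 105) and dnj-13 (rank 162). Translation factors had 9 of 40 members occupied (odds ratio 8.12, exact adjusted p = 3.59e-05), among them the initiation factor gene eif-3.C (rank 88), iff-2 (rank 121) and the elongation factor genes eef-1A.2 (rank 360) and eef-2 (rank 381). The respiratory chain list had 9 of 43 occupied (odds ratio 7.40, exact adjusted p = 5.39e-05), with cox-5A (rank 24), the ATP synthase gene atp-1 (rank 157), the succinate dehydrogenase gene mev-1 (rank 410) and cox-5B (rank 650). In the splicing list, to which REPO-1 itself belongs, 8 of 63 genes were occupied (12.7%, odds ratio 4.06, exact adjusted p = 0.00476), the strongest being smu-1 (rank 179), lsm-6 (rank 207), the DEAH-box helicase gene mog-4 (rank 293) and lsm-3 (rank 323). The lsm-3 peak lay inside the gene at an internal transcript start and also counts at the gene's 3′ end.

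Chemoreceptor and C-type lectin genes carried peaks less often than other protein-coding genes. Of 1309 chemoreceptor genes, 9 were occupied (0.688%, odds ratio 0.181, exact adjusted p = 1.46e-10), with srh-269 (signal 392.6) and sri-5 (signal 290.7) the strongest. Of 240 C-type lectin genes only clec-126 was (rank 183, odds ratio 0.114, exact adjusted p = 0.0104). The neuropeptide list had 0 of 102 (which allows a share of up to 2.94%, exact adjusted p = 0.111, but 0.0365 in the window from 1000 bp upstream) and the collagen list 1 of 180, dpy-17 (odds ratio 0.153, adjusted p = 0.0546). Collagens passed the test without replicate 1 (0 of 180, exact adjusted p = 0.00871) and among genes without a same-strand neighbour upstream (0 of 154, adjusted p = 0.0498), but with the nearest 5′ end only they had 8 of 180 (odds ratio 0.944). Lists for the tissues of the animal did not pass the test at the 5′ end: germline and oocyte 1 of 58 (egg-1), sperm 2 of 90 (spe-48 and spe-5), intestine 1 of 39 (fat-6, a fatty acid desaturase gene), muscle 2 of 47 (cap-2 and act-3) and neurons 1 of 52 (unc-31). The fat-6 and unc-31 peaks lay inside the genes, at internal transcript starts. The lists for histones (4 of 72, his-37 strongest at rank 117), proteasome subunits (3 of 33, with rpn-3 at rank 176), RNA polymerase II and elongation (2 of 26, pafo-1 and rpb-11), DNA replication (1 of 42, pcn-1 at rank 99) and nuclear hormone receptors (6 of 269, with nhr-47 at rank 170) did not pass either. Tests were Fisher's exact, two-sided, adjusted over 19 lists. Of 47 list members named by the fixed rule, 40 had a peak among the 1789 strongest of both replicates; the exceptions were his-24, rpn-11, egg-1, spe-5, act-3, unc-31 and dpy-17. Against the 5090 genes with any region of the unthresholded pooled list at the 5′ end, the splicing (odds ratio 1.53, exact adjusted p = 0.542), chemoreceptor (odds ratio 1.18, adjusted p = 0.827) and C-type lectin (odds ratio 0.196, adjusted p = 0.286) calls ended. This background comes from the same pull-down and kept 57 of the 1309 chemoreceptor genes, with all 9 occupied ones. It therefore cannot show whether chemoreceptor genes in general carry fewer peaks. In a window of 200 bp upstream to 100 bp downstream the ribosomal protein (odds ratio 3.02, exact adjusted p = 0.135), respiratory chain (odds ratio 4.25, adjusted p = 0.124) and C-type lectin (0 of 240, adjusted p = 0.0914) calls ended, the C-type lectin call also did without replicate 2 (odds ratio 0.246, adjusted p = 0.0726) and at or above the median signal (odds ratio 0.209, adjusted p = 0.204). Among genes without a same-strand neighbour upstream the splicing (4 of 44, odds ratio 3.30, exact adjusted p = 0.0962) and C-type lectin (1 of 202, odds ratio 0.161, adjusted p = 0.0908) calls ended. Counting only the nearest 5′ end, the chaperone odds ratio was 4.18 (10 of 59, exact adjusted p = 0.00145), and against genes with a pooled region the odds ratios that kept their call were 3.66 for ribosomal proteins, 4.07 for chaperones, 5.21 for translation factors and 3.37 for the respiratory chain. Without replicate 1 the splicing list had 12 of 63 occupied (odds ratio 6.76, exact adjusted p = 7.81e-06).

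**Figure D4:**
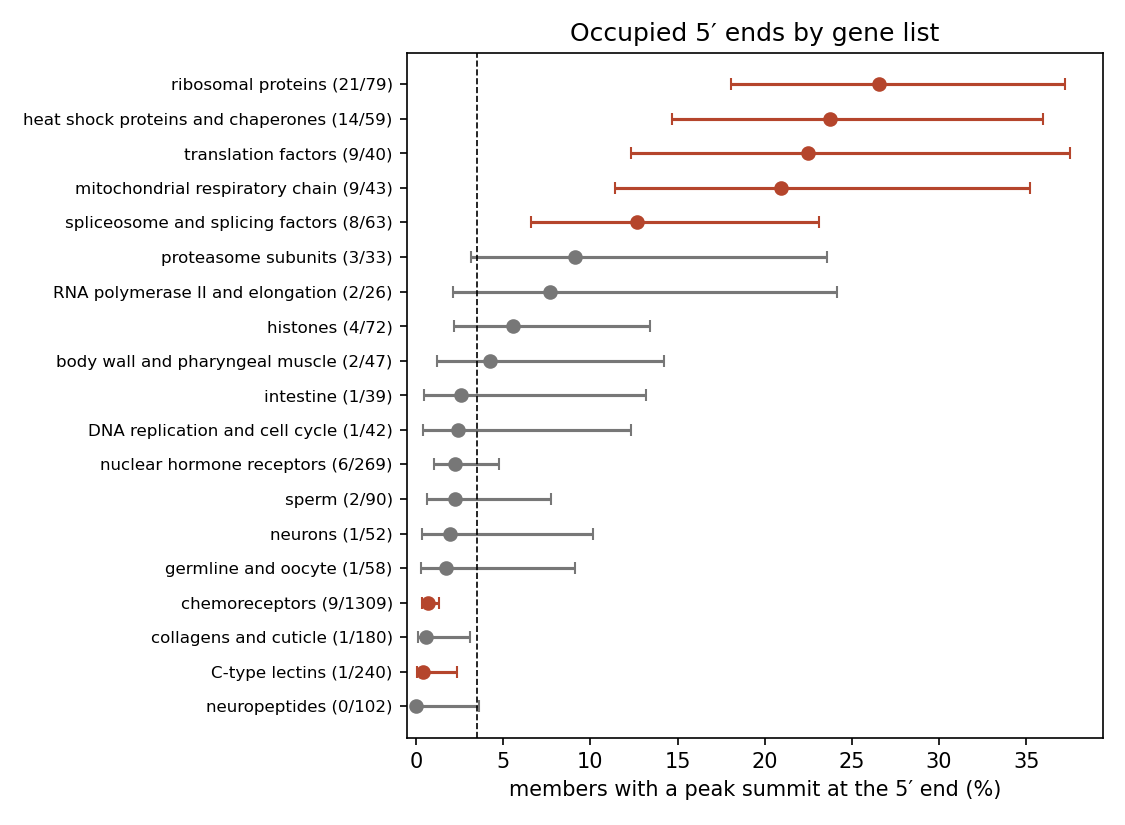
Percentage of members of each gene list with a replicated REPO-1 summit at the 5′ end, with Wilson 95% intervals and occupied over total members in brackets; red marks lists past an adjusted p threshold of 0.05, and the dashed line the share of all 19973 protein-coding genes, 3.49%. Ribosomal proteins stand at 26.6% and chemoreceptors at 0.688%.

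Genes of small structural RNAs were among the most often occupied. Of 612 tRNA genes, 199 had a summit at the 5′ end (32.5%, interval 28.9 to 36.3), against 3.49% of protein-coding genes (odds ratio 13.3, Fisher's exact test, adjusted p = 5.45e-121), and the strongest such peak (X: 3036050 to 3036235, rank 54) had its summit, at 3036122, between a pair of divergent tRNA genes and covered the one on the plus strand. snoRNA genes, whose products guide modification of ribosomal RNA, were occupied in 84 of 346 cases (24.3%, odds ratio 8.87, adjusted p = 4.79e-43). snRNA genes, a class that here includes spliced leader RNAs, were occupied in 22 of 129 cases (17.1%, odds ratio 5.69, adjusted p = 1.93e-09), led by sls-2.4 and sls-2.1. miRNA genes followed with 22 of 261 (8.43%, odds ratio 2.55, adjusted p = 0.000315), with mir-2214 (rank 87) the strongest, and other ncRNA genes with 380 of 7864 (4.83%, odds ratio 1.40, adjusted p = 4.62e-07). piRNA genes were occupied in 37 of 15363 cases (0.241%, odds ratio 0.0668, adjusted p = 4.73e-125) and pseudogenes in 9 of 2128 (0.423%, odds ratio 0.117, adjusted p = 2.87e-20). The lincRNA class had 5 of 194 (exact adjusted p = 0.778) and rRNA genes 0 of 20, which allows a share of up to 15%. Whether reads could be placed uniquely at the rRNA genes was not examined. Fisher's exact test, two-sided, was used, adjusted over 9 classes. It treats genes as independent, but neighbouring genes can share a peak, as the tRNA pair at rank 54 does. No rotation was run for these classes, so dependence between neighbours is not reflected in these p-values and intervals. Scored within 200 bp of the gene on either side, other ncRNA genes fell below protein-coding genes (odds ratio 0.738, exact adjusted p = 4.26e-07) and miRNA genes no longer differed (odds ratio 0.894, adjusted p = 0.799), while tRNA and snoRNA genes kept their calls with odds ratios of 6.96 and 4.27, and at or above the median signal the miRNA call ended (odds ratio 1.80, adjusted p = 0.139). Scoring over the whole gene makes the target depend on gene length, so the classes were not compared over equal windows. The tRNA and snoRNA odds ratios fell too, so the reversal does not show that other ncRNA genes carry fewer peaks.

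**Figure D5:**
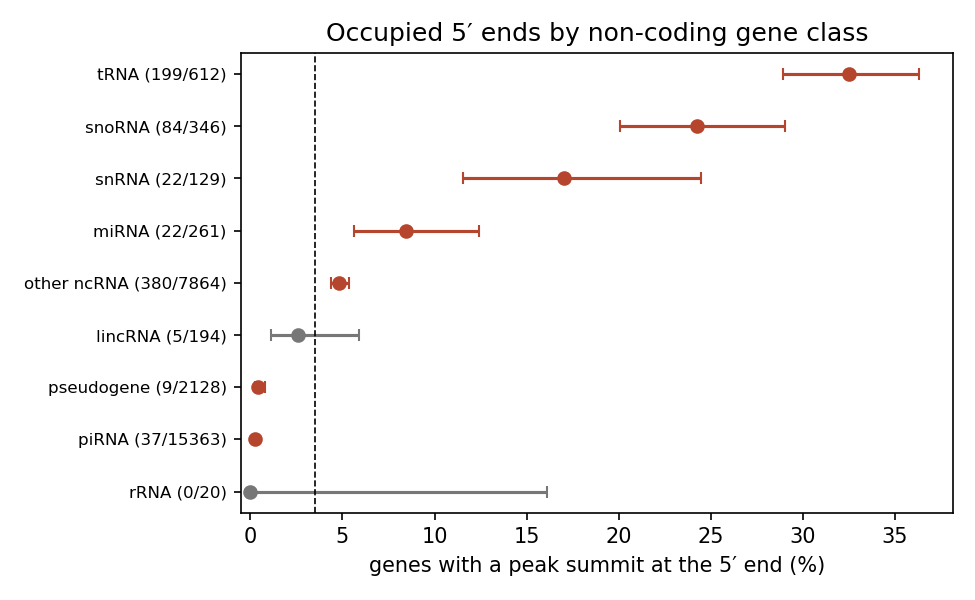
Percentage of genes of each non-coding class with a replicated REPO-1 summit at the 5′ end, with Wilson 95% intervals and occupied over total genes in brackets; red marks classes past an adjusted p threshold of 0.05, and the dashed line the share of protein-coding genes, 3.49%. tRNA genes stand at 32.5%, snoRNA genes at 24.3% and piRNA genes at 0.241%.

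Protein-coding genes on X were occupied less often than autosomal genes, and intronless genes less often than genes with introns. On X, 60 of 2731 protein-coding genes carried a summit at the 5′ end (2.20%), against 637 of 17242 on autosomes (3.69%; odds ratio 0.586, Fisher's exact p = 3.92e-05). The share by chromosome was highest on III (5.27%, interval 4.48 to 6.18) and 2.38% on V. When occupied calls were rotated along the gene order, which keeps neighbouring genes together, the X difference did not pass the permutation test (p = 0.210). In the middle of 3 equal parts of each autosome 279 of 6568 genes were occupied (4.25%), against 358 of 10674 in the outer parts (3.35%; odds ratio 1.28, Fisher's exact p = 0.00275), and this difference too was not past the threshold under rotation (p = 0.179) or at or above the median signal (odds ratio 1.16, p = 0.202). Of 685 protein-coding genes without an intron in any transcript, 9 were occupied (1.31%), against 688 of 19288 with introns (3.57%; odds ratio 2.78, Fisher's exact p = 0.000627). Among genes with introns the share varied little with their number, from 3.28% at 3 to 5 introns to 3.99% at 10 or more. In the window of 200 bp upstream to 100 bp downstream the intron difference gave an odds ratio of 2.05 (Fisher's exact p = 0.0995), and at or above the median signal it gave 4.64 (p = 0.00109).

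Sequence at REPO-1 summits was richer in G+C than promoters without a peak. Within 100 bp of 1789 summits the G+C share was 42.6% ± 7.74 (SD), against 34.1% ± 6.41 in windows from 300 to 100 bp upstream of 19276 unoccupied protein-coding genes, a difference of 8.50 percentage points (permutation test with 100000 resamples, p = 1e-05, the smallest it can give). Shifted summits had a mean of 35.4%. The summits were of all annotation classes, with 34.2% in promoter windows, so the difference mixes sequence class with occupancy. Occupied promoters were not compared with unoccupied ones on their own. The observed over expected CpG ratio was 1.12 at summits, 1.05 at unoccupied genes (same permutation test, p = 1e-05) and 1.01 at shifted summits.

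At the gene of the tagged protein itself, repo-1 (WBGene00008683, IV: 12084478 to 12085320, plus strand), no peak was listed. The window of 40 kb centred on repo-1 held 0 peaks of the replicated list and 0 of the 30000 summits of the unthresholded pooled list, which placed its summed signal at percentile 2.32 of 20008 windows of that size, where the median window summed to 717.7. In the replicates' own lists the window was likewise empty. Within 80 kb the pooled list had 9 regions, at percentile 14.5. The lists derive from the replicates' alignments and a further alignment not used here, so an empty window does not give the read level of the pull-down at this gene, and extra copies of the region in the strain could not be judged from it.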

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

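The 3′ end window and the counting of repeated regions once were chosen after the data were seen, and the other settings before. Directions and calls for peak position in promoters, the 3′ part of genes and base composition were kept under every alternative run for them. Of the non-coding classes, 7 had a call, against 6 within 200 bp of the gene and 6 at or above the median signal. The number of replicated peaks fell by construction to 895 at or above the median signal and to 1151 with a strong peak in both replicates. The share found in both replicates was 54.4% with summits within 100 bp, 38.9% with lists halved and 90.8% with lists doubled, where the length of the lists itself limits the share. The 5′ part of genes of 4000 bp or longer, 23.04%, was no longer past the threshold. X against autosomes (odds ratio 0.586) and centres against outer parts (1.28) lost their call under rotation, and the latter also at or above the median signal (1.16). The intron difference lost it in the narrow window (2.05). For all of these the cause was not tested. Called lists numbered 7, but 4 in the narrow window and 4 against genes with a pooled region. The repo-1 window stood at percentile 7.84 at 20 kb and 14.5 at 80 kb, and from 1.38 to 2.19 in single replicates.

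Of 190 list values, 149 kept direction and call, 9 kept direction but lost the call, 4 kept direction and gained one, and 28 changed direction. Of those that changed direction, germline and intestine gained a call in the 3′ end window, and chemoreceptors lost theirs against genes with a pooled region, a background taken from the same pull-down. With the nearest 5′ end only, odds ratios became 0.883 for histones, 1.56 for replication, 1.11 for germline, 2.998 for intestine and 0.903 for muscle. At or above the median signal they were 0.708 for histones, 1.23 for replication and 1.33 for intestine. In the wide window they were 1.03 for replication, 1.13 for germline and 0.918 for muscle, and in the narrow window 1.28 for sperm, 1.48 for intestine and 0 for muscle. From single replicates they ran from 0.721 to 2.18 for replication, 0 to 1.01 for germline, 1.60 to 2.36 for intestine and 0.614 to 1.32 for muscle. Against genes with a pooled region they were 0.995 for proteasome, 1.05 for sperm, 0.629 for muscle and, for the called chemoreceptor list, 1.18. In the 3′ end window they were 0.928 for histones, 4.49 for germline, 6.46 for intestine, 1.78 for neurons and 1.34 for neuropeptides. Within 200 bp of the gene, miRNA genes had 0.894 and other ncRNA genes 0.738, the latter with a call in the opposite direction. The target in this setting depends on gene length, so that call does not show fewer peaks at these genes. No paired analysis was possible because there was 1 group. Of 118 checks of named genes in single replicates, 111 kept a peak among the 1789 strongest. Depth, which is unknown here, and the number of replicates limit how weak a peak could be listed.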

Other observations

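Apart from the motif and shuffled motif comparisons at X summits outside promoters, the comparisons of tRNA genes far from promoters and of tRNA genes unique with their flanks, and the percentile of the repo-1 window, the tests in this part were chosen after the result was seen, as were the genes named at 3′ ends. Gene 3′ ends were occupied in more genes than 5′ ends. In the window from 200 bp upstream to 500 bp downstream of a transcript 3′ end, 894 protein-coding genes had a summit, against 697 at the 5′ end, and 131 genes had both. The 894 include 3′ ends near another gene's 5′ end or a non-coding gene, and the difference from 5′ ends was not tested. Away from such neighbours 319 of 9221 genes were occupied at the 3′ end, while the 5′ share over all protein-coding genes was 3.49%. Of ribosomal protein genes 32 of 79 were occupied at the 3′ end (40.5%, odds ratio 15.03, exact adjusted p = 9.76e-22), of proteasome genes 12 of 33 (odds ratio 12.3, adjusted p = 5.66e-08), of respiratory chain genes 13 of 43 (odds ratio 9.37, adjusted p = 1.32e-07), of chaperone genes 14 of 59 (odds ratio 6.73, adjusted p = 9.02e-07), of splicing genes 14 of 63 (odds ratio 6.18, adjusted p = 1.79e-06) and of translation factor genes 7 of 40 (odds ratio 4.55, adjusted p = 0.0038). Of the lists for tissues, none of which had a call at the 5′ end, intestine and germline passed here: intestine with 9 of 39 (odds ratio 6.46, exact adjusted p = 0.000119), including the yolk protein genes vit-2 (rank 97), vit-6 (rank 182) and vit-5 (rank 279, a peak with its summit in an intron of unc-78 that also counts at the 3′ end of that muscle gene) and the cathepsin B-like gene cpr-6 (rank 69), and germline and oocyte with 10 of 58 (odds ratio 4.49, adjusted p = 0.000539), including the eggshell proteoglycan gene cpg-1 (rank 100), cgh-1 (rank 544), csr-1 (rank 571) and cbd-1 (rank 812). Muscle (5 of 47, odds ratio 2.55, exact adjusted p = 0.0917), neurons (4 of 52, odds ratio 1.78, adjusted p = 0.431) and sperm (3 of 90, odds ratio 0.735, adjusted p = 0.894) did not pass. Chemoreceptor genes were occupied in 3 of 1309 cases (odds ratio 0.0458, exact adjusted p = 9.76e-22) and C-type lectin genes in 3 of 240 (odds ratio 0.268, adjusted p = 0.0206), the latter not past the threshold under rotation (adjusted p = 0.0513). All but the rotation were Fisher's exact tests, two-sided, over 19 lists. Among genes with a peak at 1 end only, the difference from other genes in the share at the 3′ end was not past the threshold after adjustment for intestine (8 at the 3′ end only and 0 at the 5′ end only), germline (10 and 1) or proteasome (10 and 1), each with an adjusted p of 0.157 (Fisher's exact test).

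Of 18 SL2 RNA genes, 8 had a summit at the 5′ end (44.4%, Wilson 95% interval 24.6 to 66.3), against 0 of 12 SL1 RNA genes, which allows a share of up to 25%, and 14 of 99 other snRNA genes (14.1%). The difference between SL2 and SL1 genes was not tested. Repeated sequence was examined only for tRNA genes, so the 0 at SL1 RNA genes may not mean that peaks are absent there. A test planned before the data were examined asked whether extra copies of the tagged region in the strain raised peak signal around repo-1. The prediction, a percentile at or above 95, was not met: the 40 kb window was empty, at percentile 2.32 of the pooled list. This decides nothing about extra copies, because copies in the further alignment behind the lists, which was not used here, could also empty the window.

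Peaks at 3′ ends could belong to promoters of neighbouring genes in a compact genome, but among 9221 genes with a 3′ end more than 1000 bp from any protein-coding 5′ end and clear of non-coding genes, 319 were occupied, 2.72 times the mean of 117.5 for shifted summits, against 3.51 times for all 3′ ends (permutation p = 0.002, the smallest that 1000 shifts can give). In that set the proteasome (5 of 12, adjusted p = 0.000296), respiratory chain (5 of 17, adjusted p = 0.00134), splicing (5 of 22, adjusted p = 0.0037), intestine (4 of 20, adjusted p = 0.0142), germline (5 of 32, adjusted p = 0.0142), translation factor (3 of 12, adjusted p = 0.017) and ribosomal protein lists still passed, the last with only 4 genes in the set and 2 of them occupied (adjusted p = 0.017), and the chaperone list did not (3 of 22, odds ratio 4.44, adjusted p = 0.0738, Fisher's exact test). Short genes whose ends lie close together do not account for it either, since in genes of 4000 bp or longer 29.3% of gene-body summits were in the last of 5 parts, against 20.1% of shifted summits (permutation p = 0.002). A candidate explanation that stays open is that pull-downs recover heavily transcribed DNA whatever the tagged protein, since no input, untagged strain or expression table was used here, and association with transcribed genes during splicing is open for the same reason. No biological explanation was tested, because the design has 1 group.

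The top 100 held 22 of the 300 X summits, and all 22 lay outside promoter windows. Among summits outside promoter windows, 22 of 244 on X were in the top 100, against 42 of 934 autosomal ones (odds ratio 2.10, Fisher's exact p = 0.0102). A hypothesis from the positions was that such X peaks are recruitment sites of the X dosage compensation complex, which carry, from background knowledge, the 12-base motif TCGCGCAGGGAG. With up to 2 mismatches within 100 bp of the summit, the motif was at 16 of the 244 X summits (6.56%) and 7 of the 934 autosomal summits (0.749%), an odds ratio of 9.29 (Fisher's exact p = 4.52e-07), and 0 of 100 shuffled motifs matched as many X summits, the highest reaching 10, so base composition of the motif alone is unlikely to account for it. Of these 16 sites, 13 were in the top 100, among them rank 8 (X: 11094123 to 11094134, minus strand, intergenic) and rank 21 (X: 2997121 to 2997132, minus strand, intronic), both with an exact match, and the 6-mer most enriched at X summits outside promoters and non-coding genes, GCAGGG (23 of 144 against 15 of 689 autosomal, adjusted p = 1.94e-06), lies inside the motif. Neighbouring summits were counted separately, as at ranks 21 and 564 (summits X: 2997067 and 2997274), although Fisher's test treats summits as independent. The 6-mer was counted at the same X summits and in part at the same motif matches, so it is not independent of the motif count. These values are consistent with peaks at recruitment sites at some X positions, but whether REPO-1 itself binds there or such sites are recovered in pull-downs of many tagged proteins stays open, and the design has no group that would test it.

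tRNA genes carried peaks far more often than protein-coding genes, and the comparison was repeated in subsets of them. Promoters nearby are unlikely to be the source: 381 tRNA genes with no protein-coding 5′ end within 1000 bp had an odds ratio of 13.0 against protein-coding genes (122 occupied, Fisher's exact p = 1.81e-76). The 140 tRNA genes whose own sequence occurs once in the genome had an odds ratio of 7.87 (31 occupied, Fisher's exact p = 3.03e-16), so reads shared between tRNA genes of exactly the same sequence do not account for the whole difference, although genes with repeated sequences were occupied more often (35.6% against 22.1%, Fisher's exact p = 0.00283). Genes of nearly the same sequence stay among the 140, and reads shared between such genes were not examined. The planned test, on tRNA genes unique with 100 bp on each side, left 610 of 612 genes (odds ratio 13.4) and so decided nothing. Neighbouring tRNA genes that share a peak were counted separately in these tests. Recovery of heavily transcribed DNA in any pull-down stays open, and no biological explanation was tested.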
